A study of Mus musculus with 19 samples.

How the data were processed

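Nuclei were isolated from dissected preoptic tissue of C57BL/6J mice, libraries were made with the 10x Genomics 3' v3 chemistry, and sequencing was run on a NovaSeq 6000, per the labels. The submitters' processing notes name Cell Ranger and the mm10 build, and the Cell Ranger version is not given in the sources used here. The deposited matrices held raw UMI counts per gene and nucleus, whole numbers with no normalization, for the same 26421 genes in each of 19 samples, with a gene symbol and an Entrez identifier per gene. Barcodes had been filtered before deposit by a rule that is not given in the sources used here: the lowest number of genes in any barcode was 501 and the highest mitochondrial share was 3.856%. Positions are those of GENCODE M21 on mm10, matched by symbol. A group's name and the sex of each animal were taken from the labels, and the levels of Xist and of Y-linked genes matched the labelled sex in all 19 animals.

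All gene lists, marker lists, tests, thresholds and the rule for named genes were fixed before the data were examined, except where stated here. Nuclei with at least 500 genes, at least 1000 UMIs and at most 5% mitochondrial counts were kept. No barcode exceeded the mitochondrial limit, 4474 fell under the UMI minimum, and 158075 passed. Doublet scores were computed per animal with Scrublet (in scanpy 1.11.5, seed 1) at an expected rate of 0.8% per 1000 barcodes. The tool's own threshold called 0.03% to 0.53% of nuclei, so the highest scores up to the expected rate were called instead, a choice made after seeing those numbers. It called 11035 nuclei, 4.95% to 8.50% per animal.

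Counts were scaled to the total per nucleus and log transformed, 2500 variable genes were chosen by their median rank over animals, and 40 principal components gave a graph of 20 shared nearest neighbours. Leiden clustering was run with igraph 0.11.9 at resolution 1 on all nuclei, giving 50 clusters, and at resolution 1.5 on neurons, giving 55. Genes of the response lists (immediate early, clock, stress, cholesterol and similar) were left out of the clustering. So were Xist, Tsix, Y-linked genes, mitochondrial genes and ribosomal protein genes, while X-linked genes as a group were not. No integration across animals was used. Clusters with over 30% called doublets (6) and single called doublets were removed, which left 145410 nuclei. Clusters of all nuclei were named from marker lists with at least 3 markers present. Neuronal clusters were named inhibitory when their CPM of Slc32a1 was over 2 times that of Slc17a6, and excitatory in the reverse case. The name also needed at least 3 markers of that class present. Among the genes that most set the cluster apart, markers of the other class could not outnumber its own. This rule replaced one on all markers after the clusters, but no sleep comparison, had been seen. It left 5 clusters without a name, among them clusters 3, 8, 21 and 38, with 64.6 to 70.5 CPM of Slc32a1 and 7.8 to 9.6 CPM of Slc17a6. Clusters 3, 8, 21 and 38 passed the factor for Slc32a1 but not all of the other conditions. Cluster 39, with the acetylcholine genes Chat and Slc5a7 (1024 nuclei), was named cholinergic. These 6 are part of the neurons but of neither class. A cluster was called galanin-rich when its mean Gal CPM was at least 3 times the mean over all neurons. Neuronal clusters with at least 20 nuclei in at least 15 animals were tested, 42 in all.

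For genes, raw UMIs were summed per animal over the nuclei of a class (at least 20 nuclei per animal) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, sex and sleep as terms, and Benjamini-Hochberg adjusted p below 0.05. Levels in the text are CPM (UMIs of a gene scaled to a fixed total per animal and class) per animal, as mean ± SD, and fold changes are fitted values. The interaction of sex and sleep and the difference between females and males were tested the same way in all neurons. For the activity measure, UMIs of 15 core immediate early genes were summed per animal and cluster, scaled to CPM, and log2 transformed with a pseudocount of 1. The difference of recovery and normal sleep, averaged over the sexes, was tested by exact two-sided permutation of sleep labels within sex, over all 31752 assignments where all 19 animals entered, whose smallest p is 3.1e-05. Animals with too few nuclei were missing from 5 of the 42 clusters: clusters 23, 27 and 39 had 15876 assignments (smallest p 6.3e-05), cluster 44 had 4410 (0.00023) and cluster 28 had 1960 (0.00051). Adjustment was by Benjamini-Hochberg over each family: the 42 clusters, the galanin-rich clusters, or the 11 classes for shares of nuclei. Shares were tested on the logit scale.

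The 19 gene lists were core immediate early, other activity-induced, circadian clock, glucocorticoid-induced, endoplasmic reticulum stress, heat shock, cold-inducible, cholesterol synthesis, myelin, neuropeptide, adenosine and prostaglandin signalling, synaptic scaffold, sleep-regulating kinase and channel, thermoregulatory preoptic, microglial reactive, astrocyte reactive, oxidative phosphorylation, ribosomal protein and mitochondrially encoded genes. They were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and again with an estimated correlation. Single members were adjusted over all genes tested and, separately, over the list alone. The permutation of mean list levels, the tests of single core genes, the split of cluster 9 into parts and the comparison of quality measures between groups were added after the main results had been seen.

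Named genes were those past the threshold with the same sign in each sex and a mean of at least 10 CPM in the higher group. Of these the 10 largest rises and 10 largest falls were taken for all nuclei, inhibitory and excitatory neurons, and the 5 and 5 for other classes. A fixed set of 17 genes (such as Gal, Fos and Fkbp5) and up to 4 members per list with the smallest p were added whatever their p; of these the text gives the ones that passed and those needed for a comparison. Predicted gene models were counted but not named. Some genes that the rule takes are counted but not reported here. UMIs per nucleus are the summed counts of a gene in a class divided by its nuclei, per animal and then averaged over animals; a level alike in a class that should lack the gene was read as background. For the sexes, the rule took 6 sex-linked genes and the 5 largest autosomal differences each way. Genes outside the rule that the text names are Gm5820, 9630014M24Rik, Gm46102, 1700016P03Rik and Gm4876, named after their values were seen, and the sex-linked genes Kdm6a, Eif2s3x, Ddx3x, Kdm5c and Sytl4.

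The code was tested on simulated data: negative binomial counts with the means, library sizes and dispersions of the real tables, independent between genes, in which 200 genes had a planted change. At a log2 fold of 1, 90% were recovered in all nuclei, 95% in inhibitory neurons, 96% in excitatory neurons, 97% in galanin-rich neurons, 96% in astrocytes, 97% in oligodendrocytes and 95% in oligodendrocyte precursors. At 0.5 the shares were 71%, 72%, 78%, 56%, 62%, 56% and 46%. False calls numbered 1 to 10 per table. A planted fall of 0.3 in the cholesterol list was called with 0 other lists called. As the simulated genes were independent, that result does not show how often camera calls lists falsely in the real counts. The permutation test gave an unadjusted p below 0.05 in 5.2% of 400 simulated clusters without a change and in 99.8% with a log2 change of 0.8. Those levels had an SD of 0.35 on the log2 scale. Wider spreads, smaller changes and the adjustment over clusters were not simulated. Counts of free RNA in droplets were not modelled.

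Alternatives covered DESeq2's size factors in edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, a term for replicate number, no term for sex, a term for the number range of the animals, each animal left out in turn, nuclei with at least 2000 UMIs, doublets kept, a pseudocount of 10, Fos alone, clustering at resolutions of 0.8 and 3, an estimated correlation, and, chosen after the data had been seen, leaving out normal sleep male replicate 4 and normal sleep female replicate 4, which had few glia, fitting each galanin-rich cluster alone, and a term for the share of cluster 16. No 2 animals of a group had identical counts in any of 36 pairs. The labels give no sequencing batch or date. Clusters of newly formed oligodendrocytes, leptomeningeal and ependymal cells were counted in the shares but not tested for genes.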

Results

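Single nuclei from the preoptic area, a hypothalamic region that holds neurons active in sleep and in body temperature control, were sequenced from 19 mice. The labels put 9 mice in undisturbed sleep late in the light phase (normal sleep, 5 males and 4 females) and 10 mice in recovery sleep after sleep deprivation (5 males and 5 females). Each animal was 1 library, and the animal was the replicate in every test. The files held 162549 barcodes, from 6181 to 10620 per animal. In normal sleep males replicates 1 to 5, total UMIs were 33127674, 33604118, 29894593, 22896290 and 29964476. In normal sleep females replicates 1 to 4 they were 34644313, 35264250, 36390582 and 34474289. In recovery sleep males replicates 1 to 5 they were 31494500, 36569319, 31480240, 31971558 and 36510321. In recovery sleep females replicates 1 to 5 they were 28456014, 32967842, 33067321, 33516744 and 31382531. Median UMIs per nucleus ranged from 2525 to 4451 between animals.

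After filtering, 145410 nuclei remained, of which 118063 were neurons. Neurons formed 55 clusters: 36 were inhibitory by their marker genes, 13 excitatory and 1 cholinergic, and 5 had no such name. Of the other classes, astrocytes gave 11818 nuclei, oligodendrocytes 10428, oligodendrocyte precursors 1935 and microglia 729. A further 515 nuclei of all-nuclei cluster 43 carried both endothelial and pericyte markers, so that group is named by its number. Neurons made up 82.3% ± 6.55 of nuclei in normal sleep (SD, n = 9) and 80.7% ± 3.22 in recovery sleep (n = 10). None of 11 class shares changed in two-sided exact permutation tests within sex, where 0 had an unadjusted p below 0.05 and the smallest p was 0.111, for astrocytes (7.36% ± 2.29 against 8.67% ± 0.989, higher in 9 of 10 recovery animals).

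Galanin, encoded by Gal (Entrez gene 14419; mm10, chromosome 19, 3409915 to 3414544), is an inhibitory neuropeptide of sleep-active preoptic neurons. Neuronal clusters 9 and 16 were rich in its RNA and were therefore the galanin-rich clusters of every comparison at the main clustering resolution. At resolutions of 0.8 and 3 the same rule picked galanin-rich clusters anew, so those alternatives covered other sets of nuclei. Cluster 9 (4189 nuclei) had 145.8 CPM of Gal against 43.6 in all other neurons, and cluster 16 (3279 nuclei) had 198.3 against 42.9. Both carried the GABA transporter gene Slc32a1 and little of the glutamate transporter gene Slc17a6 (69.2 and 9.2 CPM in cluster 9). Cluster 9 was set apart by Csta2, Gpc4, C1ql3, Col8a1 and Ecel1, and held 79.7 CPM of the calcitonin receptor gene Calcr. Cluster 16 was set apart by Acss3 and Plekhg1, and held 287.5 CPM of the oestrogen receptor gene Esr1, 178.4 CPM of the progesterone receptor gene Pgr and 90.3 CPM of Calcr. Cluster 9 made up 3.4% ± 0.918 of neurons in normal sleep (n = 9) and 3.67% ± 0.836 in recovery sleep (n = 10; exact permutation p = 0.576, adjusted p = 0.861).

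The main comparison asked which preoptic neurons are more active during recovery sleep than during sleep under low pressure, with the summed level of 15 core immediate early genes as the measure of recent activity. In neuronal cluster 9 these genes rose from 71.5 ± 12.3 CPM (SD, n = 9) to 126 ± 19.7 CPM (n = 10), a log2 difference of 0.80 (exact permutation p = 9.45e-05, two-sided, adjusted p = 0.00397 over 42 clusters). All 10 of 10 recovery animals lay above the normal sleep mean. The rise was 0.62 in females and 0.98 in males, and the test of that difference did not pass (exact permutation p = 0.436). Cluster 9 was the 1 cluster called among the 42 tested. In the other 41 clusters the median log2 difference was -0.23, the range ran from -0.64 to 0.15, and 37 clusters had a difference below 0. Of these, 6 had an unadjusted exact permutation p below 0.05, all with lower levels in recovery sleep, and none passed adjustment. The lowest adjusted p among them was 0.0589, for excitatory cluster 17, marked by the transcription factor genes Lhx1 and Trp73 (62.5 ± 17.6 CPM against 44.1 ± 6.32, log2 difference -0.47). In normal sleep females replicates 1 and 2, neurons outside cluster 9 had 100.07 and 117.43 CPM of the core genes. The other normal sleep animals had 42.82 to 76.52 CPM and recovery animals 44.48 to 66.25. These females thus contribute to the lower levels outside cluster 9 in recovery sleep, and leaving out both at once was not tested. The number of clusters called was 2 at a clustering resolution of 0.8 and 3 at a resolution of 3, and 2 or 3 without normal sleep male replicate 2 (3), normal sleep female replicate 3 (3), recovery sleep male replicate 3 (2) or recovery sleep female replicate 2 (2). Cluster 9 was called with each of the 19 animals left out. With a replicate block, in which signs were flipped within pairs of equal number, 0 of 42 clusters passed, and such pairs cannot give a p below 0.00391.

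**Figure D1:**
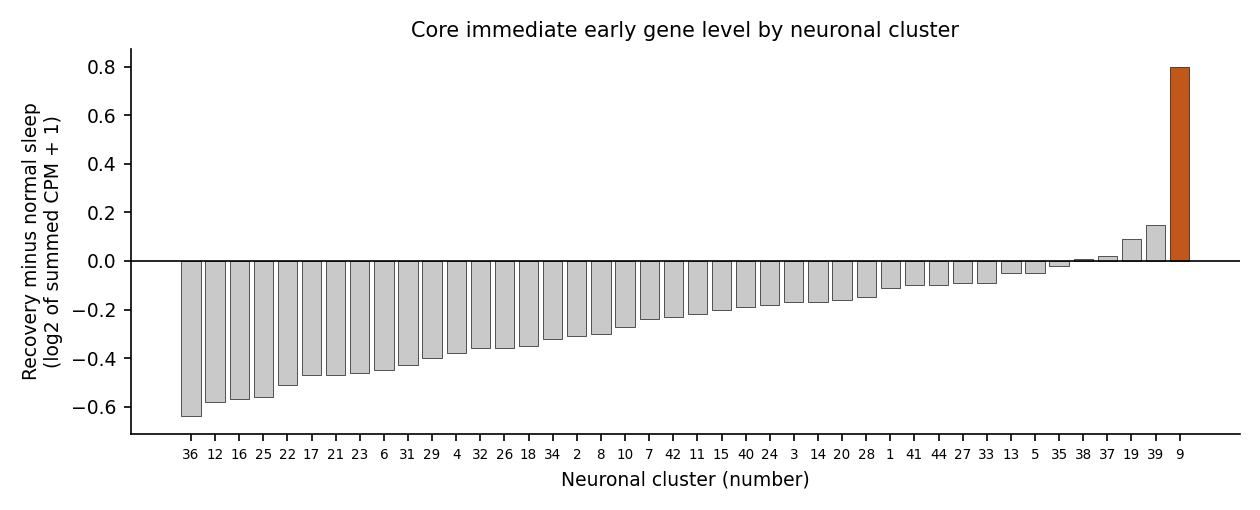
Each bar is 1 neuronal cluster, and its height is the mean log2 difference of summed core immediate early gene CPM between recovery and normal sleep. The coloured bar, cluster 9 at 0.80, is the cluster that passed the adjusted threshold, and the other 41 bars lie between -0.64 and 0.15.

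With the galanin-rich clusters tested as a family of their own, cluster 9 rose (adjusted p = 0.000189) and cluster 16 fell, from 62.6 ± 28.3 CPM (n = 9) to 40.4 ± 7.77 CPM (n = 10; log2 difference -0.57, exact permutation p and adjusted p = 0.0118, lower than the normal sleep mean in 10 of 10 recovery animals). The log2 difference in cluster 16 was -0.90 in females and -0.23 in males. Its normal sleep mean was raised by females replicates 1 and 2, with 86.27 and 124.12 CPM. The other normal sleep animals had 32.05 to 68.66 CPM there, and recovery animals 29.96 to 49.19. Over the 42 clusters the adjusted p of cluster 16 was 0.117. All neurons together had 68.0 ± 25.8 CPM of these genes in normal sleep and 54.9 ± 5.59 in recovery sleep (exact permutation p = 0.149). Measured against all other neurons of the same animal, cluster 9 rose by 1.12 in each sex (exact permutation p = 3.1e-05, the smallest these permutations can give; adjusted p = 6.3e-05). This measure also takes in the high levels of other neurons in normal sleep females replicates 1 and 2. On that measure cluster 16 had a difference of -0.32, which did not pass (exact permutation p = 0.0682). Gal itself did not pass in cluster 9 (167 ± 125 against 135 ± 25.6 CPM, adjusted p = 0.79 by exact permutation) or in cluster 16 (247 ± 216 against 184 ± 44.9 CPM, adjusted p = 0.79). In normal sleep, replicate 5 of the males stood apart with 491 CPM of Gal in cluster 9 and 807 CPM in cluster 16. The log2 differences of -0.08 and -0.13 in Gal became 0.12 and 0.07 without this animal.

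**Figure D2:**
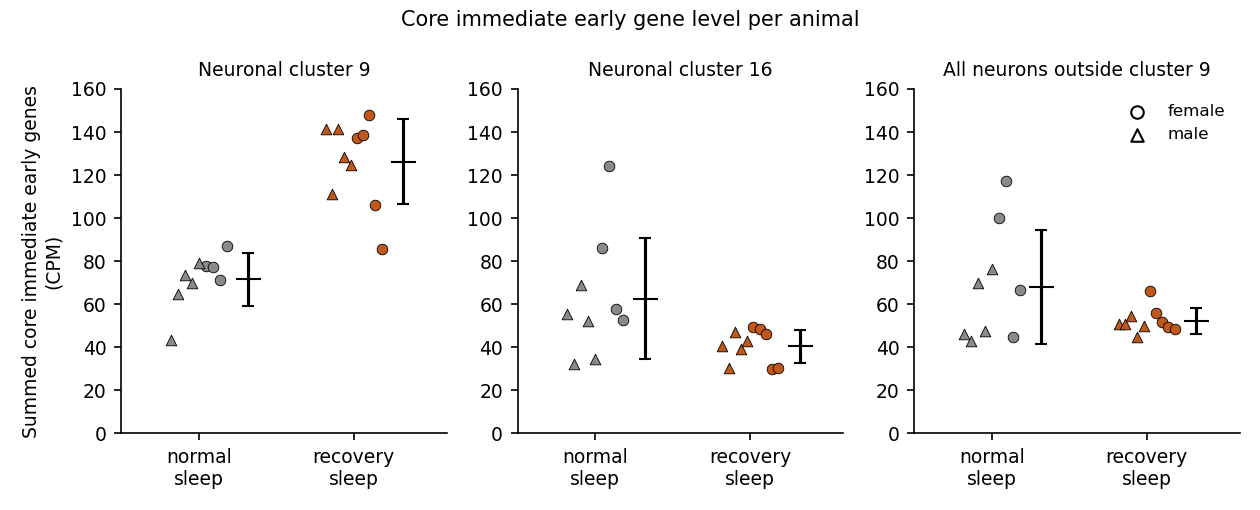
Points are animals (circles females, triangles males), the vertical axis is summed CPM of 15 core immediate early genes, and bars show mean and SD. In cluster 9 the means were 71.5 in normal sleep and 126 in recovery sleep, while in cluster 16 they were 62.6 and 40.4.

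Within cluster 9, 6 of the 15 core genes rose when tested singly, and 0 of 15 changed in cluster 16 (exact permutation, adjusted over the 15 genes, with 0 unadjusted p below 0.05 in cluster 16; a test chosen after the summed level had been seen). Egr1, a zinc finger transcription factor gene (Entrez gene 13653; mm10, chromosome 18, 34859823 to 34864984), rose from 3.98 ± 2.25 to 13.3 ± 3.50 CPM (log2 difference 1.68, adjusted p = 0.000472, above the normal sleep mean in 10 of 10). Fosl2 and Fosb, members of the AP-1 family, rose by 1.76 and 1.6, from low levels. Fosl2 was at 1.93 ± 2.24 and 7.06 ± 2.24 CPM (85 UMIs in all). Fosb was at 0.961 ± 0.883 and 5.28 ± 2.90 CPM (58 UMIs in all). Npas4, a neuron-specific factor induced by calcium entry, rose by 0.78 (adjusted p = 0.00315), the nuclear receptor gene Nr4a1 by 0.62 and the phosphatase gene Dusp1 by 0.81. Fos was at 6.02 ± 3.37 CPM and 12.9 ± 5.87 CPM (log2 difference 0.95, exact permutation, adjusted p = 0.0566), and Arc was at 1.81 and 1.31 CPM. With Fos alone as the measure, 0 of 42 clusters and 0 of the galanin-rich clusters passed, with an unadjusted exact permutation p below 0.05 in 3 of the 42 and in 1 of the galanin-rich.

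Among all genes, 29 of 10509 changed in cluster 9 by edgeR, of which 26 rose and 3 fell. The change with the smallest p was in 1700016P03Rik (Entrez gene 668604; mm10, chromosome 11, 75172560 to 75177633), a transcript whose annotated span holds the activity-induced microRNA genes Mir212 and Mir132. It rose from 21.6 ± 6.18 CPM (n = 9) to 61.6 ± 14 CPM (n = 10; log2 fold change 1.45, adjusted p = 5.23e-08, 10 of 10 above the normal sleep mean), and was named after its values were seen. The 26 risen genes included Hcrtr2, the orexin receptor 2 gene (Entrez gene 387285; mm10, chromosome 9, 76225880 to 76323856), from 35.7 ± 12.7 to 65.9 ± 21.9 CPM (0.90, adjusted p = 0.00661, 10 of 10), and Htr2a, a serotonin receptor gene, from 23.4 ± 5.31 to 41.1 ± 10.1 CPM (0.78, adjusted p = 0.00661, 10 of 10). Cyp2j7 rose by 1.42, Rgs6, which encodes a regulator of G protein signalling, by 0.97, Abtb2 by 0.95 and Nr4a1 by 0.67. The 3 genes that fell were B3gnt2 (-0.50), Pdzrn4 (-0.37) and Clstn1 (-0.34). The core immediate early list, with 3 of 15 members measured, also passed by camera (adjusted p = 3.6e-06, and adjusted p = 0.00182 with an estimated correlation), from the same counts as the summed level above and so not as further evidence, and 40 of 100 splits of the animals, the real one included, reached the 3 lists called there.

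In cluster 16, 88 of 9873 genes changed, of which 47 rose and 41 fell. The largest falls were in Pappa (Entrez gene 18491; mm10, chromosome 4, 65124174 to 65357509), which encodes a protease that cuts IGF-binding proteins, from 67.7 ± 22.2 CPM (n = 9) to 31.3 ± 13.1 CPM (n = 10; log2 fold change -1.24, adjusted p = 6.58e-05, below the normal sleep mean in 10 of 10), and in Ltbp1, from 25.5 ± 7.77 to 11.4 ± 6.06 CPM (-1.17, adjusted p = 0.00471). Pappa was also the gene that most set apart neuronal cluster 8, at 11.5 times its level in other neurons. Whether a different mix of nuclei in cluster 16 has a share in the changes of single genes was not tested. Normal sleep male replicate 3 gave 23 nuclei to this cluster. Nrip1, a corepressor of nuclear receptors, fell from 104 ± 40.9 to 50.6 ± 21.7 CPM (-0.91). Snap29, Lix1, Plcl1, Cdh10, Ndst4 and the potassium channel gene Kcnn2 rose by 0.51 to 0.81. The cholesterol synthesis list passed as a fall in cluster 16, with 13 of 13 tested members lower (camera, adjusted p = 1.22e-07, and adjusted p = 0.0924 with an estimated correlation), where 70 of 100 splits of the animals, the real one included, gave at least 1 list. In the sum of both clusters 37 of 12346 genes changed, 21 up and 16 down, among them Hcrtr2 (0.78), Dock1 (0.66), Srrm4os (0.55) and Qrfpr, a neuropeptide receptor gene (-0.78). That count was 11 without recovery sleep female replicate 4, 15 without recovery sleep male replicate 3, 20 without normal sleep female replicate 1, 19 with no term for sex and 114 with no filter on low counts. Pappa fell in cluster 16 and had a log2 fold change of 0.09 in cluster 9 (adjusted p = 0.968), while 1700016P03Rik rose in cluster 9 and had a log2 fold change of -0.27 in cluster 16 (adjusted p = 0.761); the differences between the clusters were not tested.

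**Figure D3:**
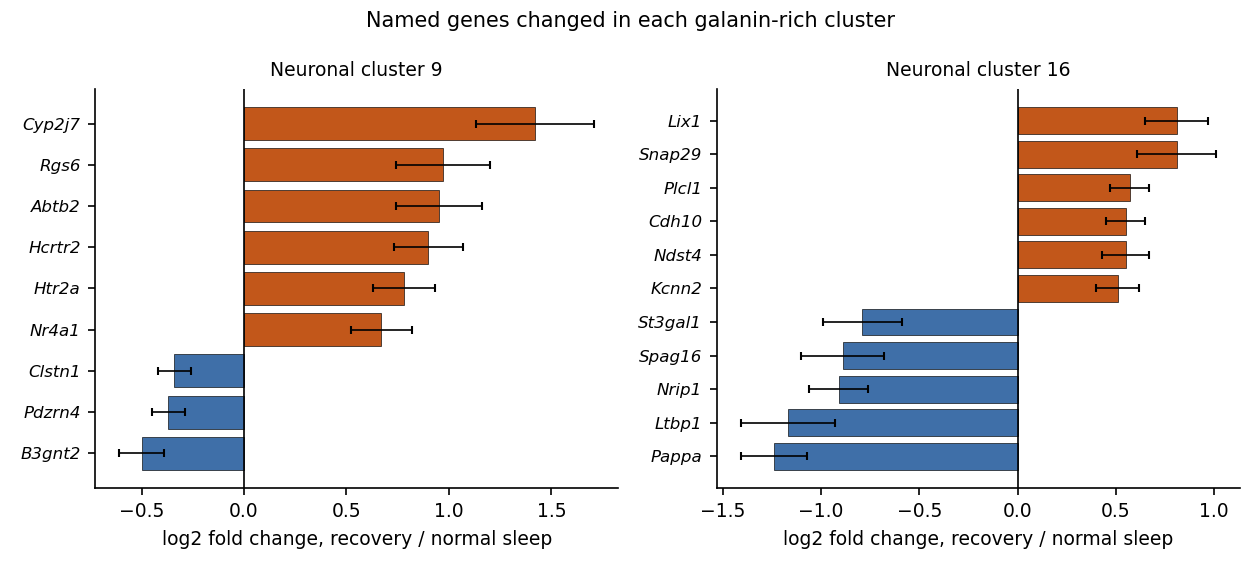
Bars are fitted log2 fold changes of recovery against normal sleep in named genes that changed in each galanin-rich cluster, and whiskers are standard errors. Cyp2j7 (1.42) has the largest change drawn for cluster 9 and Pappa (-1.24) the largest drawn for cluster 16.

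A second comparison asked which genes changed with sleep state over all neurons, by class and by fixed gene list. In inhibitory neurons 2 of 17920 genes changed: Dalrd3 rose from 107 ± 11.4 CPM (n = 9) to 142 ± 14.9 CPM (n = 10; edgeR, log2 fold change 0.42, adjusted p = 0.0206, 10 of 10), and Opalin, a gene of myelinating oligodendrocytes, fell from 8.87 ± 2.33 to 4.16 ± 0.883 CPM (-1.09, adjusted p = 0.00576, 10 of 10). Its mean UMIs per nucleus in normal and recovery sleep were 0.0372 and 0.0177 in all neurons, 0.0363 and 0.0216 in astrocytes, 0.0362 and 0.0322 in oligodendrocyte precursors (from 37 and 33 UMIs in all) and 0.462 and 0.27 in oligodendrocytes, so its level in neurons was not shown to be above background. In excitatory neurons 5 of 14905 changed. Dalrd3 rose by 0.45 and Opalin, with the same limit, fell from 8.71 to 4.32 CPM (-1.02). The predicted transcripts Gm5820 and 9630014M24Rik rose and Gm46102 fell, and these 3 were named after their values were seen. Unadjusted p was below 0.05 for 1476 genes in inhibitory and 1144 in excitatory neurons, and DESeq2 called 25 and 19. The level of Opalin in oligodendrocytes was 281 CPM in normal sleep. The 10 myelin genes had summed levels in neurons of 362 ± 77.1 and 316 ± 50 CPM (exact permutation p = 0.157).

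Cholesterol synthesis genes fell together in neurons. All 19 measured members were lower in recovery sleep, with a median log2 fold change of -0.27 (camera, adjusted p = 2.22e-16 over 19 lists, and adjusted p = 0.197 with an estimated correlation). Over all genes 1 member passed. Adjusted over the list alone 15 passed, all lower, among them Hmgcs1 (-0.33), Sqle (-0.24) and Fdps (-0.30). A permutation of the mean list level, chosen after the camera result, gave a log2 difference of -0.22 (exact permutation p = 0.00224, adjusted p = 0.0426), with 1 of 10 recovery animals above the normal sleep mean. The UMIs per nucleus of the 19 members in oligodendrocytes in normal sleep were a median of 58.3% of those in neurons and 68.2% of those in astrocytes. Summed ribosomal protein gene level in neurons was 1840 ± 467 CPM in normal sleep and 1660 ± 270 in recovery sleep (exact permutation p = 0.346).

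Glucocorticoid-induced genes passed as a rise in neurons, with 10 of 14 members higher (median 0.13; camera, adjusted p = 0.00163, and adjusted p = 0.329 with an estimated correlation). None passed over all genes, and 4 passed adjusted over the list alone: Sult1a1 (0.39), Zbtb16 (0.30), the cell cycle inhibitor gene Cdkn1a (0.62) and the lipid droplet gene Plin4 (0.58). In normal and recovery sleep the UMIs per nucleus of Sult1a1 were 0.0118 and 0.0151 in neurons, 0.0358 and 0.0794 in astrocytes and 0.00306 and 0.0128 in oligodendrocytes, and those of Cdkn1a 0.00798 and 0.0119 in neurons, 0.0162 and 0.0216 in astrocytes and 0.00593 and 0.0207 in oligodendrocytes. Those of Plin4 were 0.00603 and 0.00886 in neurons, 0.0101 and 0.015 in astrocytes and 0.0497 and 0.159 in oligodendrocytes. In precursors these 3 genes had at most 9 UMIs per sleep group, too few to set a background, so whether background has a share in their rises was not settled. Zbtb16 was at 0.156 and 0.188 in neurons, 0.217 and 0.238 in precursors, 0.259 and 0.326 in astrocytes and 0.434 and 0.555 in oligodendrocytes, so its level in neurons was not shown to be above background. The permutation of the mean level did not pass (exact permutation p = 0.0296, adjusted p = 0.187). Circadian clock genes fell, with 15 of 19 members lower (median -0.08; adjusted p = 0.0122, and adjusted p = 0.329 with an estimated correlation). Again none passed over all genes, and 4 passed adjusted over the list alone: Ciart (-0.28), Dbp (-0.38), Per1 (-0.24) and Nr1d1 (-0.31). The permutation of their mean level did not pass (exact permutation p = 0.0215, adjusted p = 0.187). Whether both sleep groups were collected at the same clock time is not given in the sources used here, and this limit holds for every clock gene value. Myelin genes passed as a fall by camera, with 10 of 10 members lower (median -0.17; adjusted p = 0.00163, and adjusted p = 0.825 with an estimated correlation), and Opalin (-1.06) was the 1 member that passed, both over all genes and adjusted over the list alone. The permutation of their mean level did not pass (exact permutation p = 0.0866, adjusted p = 0.411). Oligodendrocyte markers in neurons were at 270 ± 56.7 and 238 ± 40 CPM (-0.17), and over the 10 myelin genes the UMIs per nucleus in astrocytes were a median of 106% of those in neurons in normal sleep, so this list in neurons was not shown to be above background, except that Mbp had 0.235 UMIs per nucleus in neurons and 0.15 in astrocytes, and 0.229 in precursors.

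The other 15 lists did not pass in neurons. Core immediate early genes had 14 of 15 members lower (adjusted p = 0.0844), with Arc (-0.76) and Btg2 (-0.52) passing adjusted over the list alone. Of the other activity-induced genes, Dusp6 (-0.46) and Sik1 (-0.34) passed adjusted over the list alone, and Sik1 also passed in the list of sleep-regulating kinase and channel genes. Of the thermoregulatory preoptic genes, Esr1 (0.41) and the prostaglandin receptor gene Ptger3 (-0.24) did. Endoplasmic reticulum stress (adjusted p = 0.0576), ribosomal protein (0.0827), heat shock, cold-inducible, neuropeptide, adenosine and prostaglandin signalling, synaptic scaffold, microglial reactive, astrocyte reactive, oxidative phosphorylation and mitochondrially encoded genes had 0 members passing by either adjustment. For the other activity-induced, neuropeptide and adenosine and prostaglandin lists, camera gave a rise while the median was -0.04, 0.01 and -0.01 and the mean -0.02, -0.01 and 0.02. With an estimated correlation 0 of the 19 lists passed, and 2 had an unadjusted p below 0.05. Of 100 splits of the animals, the real one included, 67 gave at least 4 lists. The preset correlation gave 7 lists without normal sleep male replicate 1 and 7 without normal sleep male replicate 2.

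**Figure D4:**
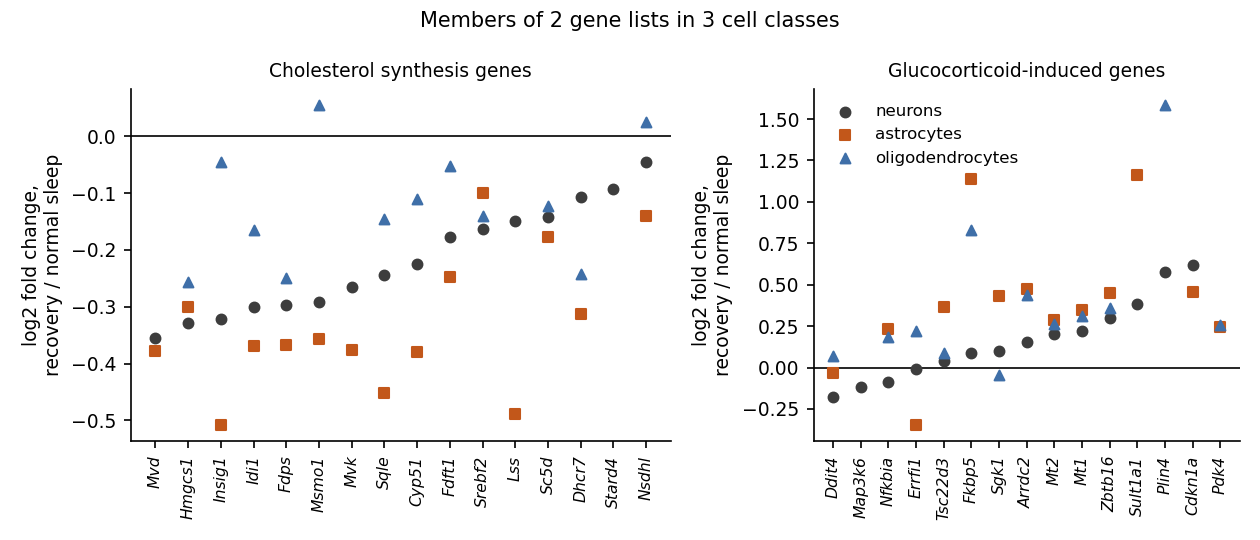
Points are fitted log2 fold changes of recovery against normal sleep for members of the cholesterol synthesis and glucocorticoid-induced lists in neurons, astrocytes and oligodendrocytes. The cholesterol synthesis members drawn lie below 0 in neurons and in astrocytes, and the glucocorticoid-induced genes lie mostly above it.

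Over all nuclei, 21 of 19551 genes changed, 20 up and 1 down. Phyhd1 rose from 17.1 ± 3.72 CPM (n = 9) to 32.6 ± 7.47 CPM (n = 10; edgeR, log2 fold change 0.92, adjusted p = 0.00182, 10 of 10), followed by the growth factor gene Pdgfd (0.83), the cyclin gene Ccnd3 (0.66), Pnpla7 (0.63), Dalrd3 (0.41) and the arrestin gene Arrb2 (0.32). Sult1a1 (0.64) and Plin4 (1.01) rose from the glucocorticoid-induced list. DESeq2 called 76 genes, nuclei with at least 2000 UMIs gave 10, and the count was 12 without recovery sleep male replicate 5.

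Astrocytes held the largest number of changes of any class in edgeR: 245 of 11239 genes, 162 up and 83 down, with the same sign in females and males for all 245. Lncbate1 (Entrez gene 109215; mm10, chromosome 8, 108553252 to 108584595), a long noncoding RNA gene, rose from 11.4 ± 9.19 CPM (n = 9) to 37.6 ± 13 CPM (n = 10; log2 fold change 2.09, adjusted p = 2.21e-08, 10 of 10). Pde10a, which encodes a phosphodiesterase of cAMP and cGMP, rose from 36.7 ± 14.8 to 145 ± 78.0 CPM (1.92, adjusted p = 4.62e-07, 10 of 10). The coagulation factor gene F5 rose by 2.48, Adap2 by 1.99 and Adap2os by 1.79. The largest falls were in Slc13a3, a dicarboxylate transporter gene (-1.21), Grm4, a metabotropic glutamate receptor gene (-1.02), Etv4, a transcription factor gene (71.4 ± 19.1 to 37.6 ± 14.1 CPM, -1.0, adjusted p = 5.34e-05, 10 of 10), Padi2 (-0.90) and Ptchd4 (-0.90). The neuron markers measured in astrocytes were at 1210 ± 267 CPM in normal sleep and 1090 ± 98.5 CPM in recovery sleep (exact permutation p = 0.394). The astrocyte share of normal sleep male replicate 4 was 1.47%; without it and normal sleep female replicate 4 the count was 202, and with no filter on low counts it was 417.

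Cholesterol synthesis genes fell in astrocytes, with 18 of 18 members lower (median -0.37; camera, adjusted p = 4.3e-10, and adjusted p = 0.217 with an estimated correlation). Over all genes 4 passed, among them Insig1 (-0.51), which encodes a regulator of sterol sensing, and 10 passed adjusted over the list alone. The mean list level fell by 0.33 (exact permutation p = 0.00243, adjusted p = 0.0219), and 0 of 10 recovery animals lay above the normal sleep mean. Glucocorticoid-induced genes rose, with 11 of 13 members higher (median 0.36; adjusted p = 1.21e-05, and adjusted p = 0.275 with an estimated correlation). Fkbp5, a cochaperone of the glucocorticoid receptor (Entrez gene 14229; mm10, chromosome 17, 28399094 to 28517527), rose from 37.3 ± 15 to 85.1 ± 33.4 CPM (1.14, adjusted p = 0.000514, 10 of 10), and Sult1a1 rose by 1.16; adjusted over the list alone 6 rose and 1 fell, Errfi1 (-0.35). The mean level of that list rose by 0.47 (exact permutation p = 0.00129, adjusted p = 0.0219, 10 of 10). Heat shock (adjusted p = 0.0241), endoplasmic reticulum stress, oxidative phosphorylation and ribosomal protein genes (each 0.0409) and neuropeptide genes (0.00896) passed as rises by camera with 0 members passing singly. With an estimated correlation their adjusted p was 0.529, 0.616, 0.616, 0.616 and 0.423, and the permutation of their mean levels did not pass (adjusted p = 0.306, 0.306, 0.483, 0.483 and 0.242). Of 100 splits, the real one included, 5 gave at least 7 lists in astrocytes.

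**Figure D5:**
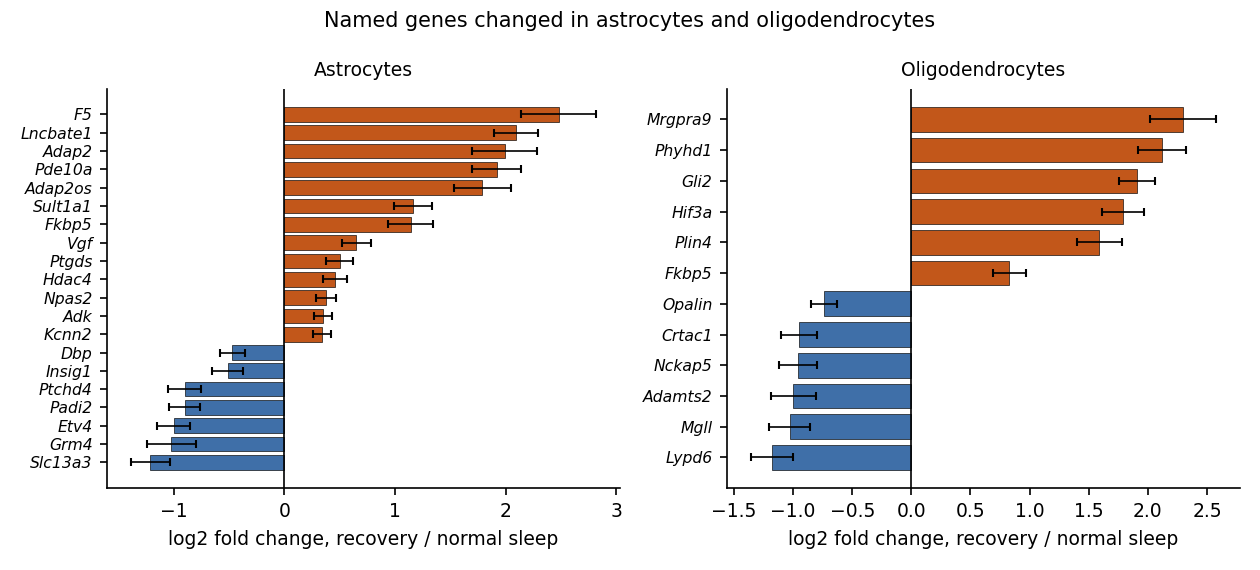
Bars are fitted log2 fold changes of recovery against normal sleep for named genes that changed in astrocytes and in oligodendrocytes, and whiskers are standard errors. F5 (2.48) and Slc13a3 (-1.21) mark the ends for astrocytes, and Mrgpra9 (2.30) and Lypd6 (-1.18) those for oligodendrocytes.

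Members of other lists also changed in astrocytes over all genes. Adk, which encodes adenosine kinase, rose from 428 ± 41.7 to 549 ± 73.5 CPM (0.35, adjusted p = 0.00832, 10 of 10), and Ptgds, which encodes prostaglandin D synthase, rose from 465 ± 101 to 664 ± 185 CPM (0.50, adjusted p = 0.0153, 9 of 10). The log2 fold change of Ptgds was 0.45 in inhibitory neurons, 0.48 in excitatory neurons, 0.50 in oligodendrocyte precursors and 0.63 in oligodendrocytes, none called over all genes. Its UMIs per nucleus were 0.917 and 1.24 in astrocytes and 0.886 and 1.21 in neurons, so its counts in astrocytes are at the level of background. The clock genes Npas2 and Dbp changed in opposite directions (0.38 and -0.47), with the clock time of collection not given. Vgf, an activity-induced gene, rose by 0.65, the potassium channel gene Kcnn2 by 0.34 and the histone deacetylase gene Hdac4 by 0.46. The remaining lists did not pass: core immediate early (2 members measured), other activity-induced, circadian clock, cold-inducible, myelin, adenosine and prostaglandin signalling, synaptic scaffold, sleep-regulating kinase and channel, microglial reactive, astrocyte reactive and mitochondrially encoded genes. For core immediate early, clock and sleep-regulating genes camera gave a rise while the median was -0.04, 0.00 and -0.02.

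In oligodendrocytes 97 of 9434 genes changed, 61 up and 36 down. Gli2, a transcription factor gene of hedgehog signalling (Entrez gene 14633; mm10, chromosome 1, 118834132 to 119053619), rose from 17.9 ± 8.27 CPM (n = 9) to 70.7 ± 18.3 CPM (n = 10; edgeR, log2 fold change 1.91, adjusted p = 4.89e-11, 10 of 10). Hif3a, which encodes a hypoxia-inducible factor subunit, rose from 24.4 ± 16.9 to 103 ± 33.9 CPM (1.79), Phyhd1 by 2.12, Mrgpra9 by 2.30 and Plin4 by 1.59. Falls were led by Lypd6 (-1.18) and by Mgll, which encodes the lipase of the endocannabinoid 2-arachidonoylglycerol (33.5 ± 14.6 to 14.7 ± 4.14 CPM, -1.03, adjusted p = 0.000333, 10 of 10), with Adamts2 (-1.0), Nckap5 (-0.96) and Crtac1 (-0.95). Nuclei with at least 2000 UMIs gave 36 genes, and the count was 63 without recovery sleep female replicate 4, 64 without recovery sleep male replicate 3 and 185 with no filter on low counts.

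Glucocorticoid-induced genes rose in oligodendrocytes, with 11 of 12 members higher (median 0.26; camera, adjusted p = 5.22e-06, and adjusted p = 0.370 with an estimated correlation). Fkbp5 rose from 78.9 ± 27.3 to 151 ± 38.5 CPM (0.83, adjusted p = 0.000407, 10 of 10); with Plin4 it made 2 over all genes, and 4 passed adjusted over the list alone. The mean list level rose by 0.51 (exact permutation p = 0.00268, adjusted p = 0.0429, 10 of 10). Myelin genes fell, with 10 of 10 lower (median -0.19; adjusted p = 0.000367, and adjusted p = 0.382 with an estimated correlation). Opalin fell from 281 ± 62.2 to 173 ± 30.9 CPM (-0.74, adjusted p = 5.95e-05, 10 of 10) and was the 1 member that passed over all genes, while Cnp (-0.43) joined it adjusted over the list alone. The permutation of the mean myelin level did not pass (exact permutation p = 0.0275, adjusted p = 0.139). Cholesterol synthesis genes had 13 of 15 members lower and 0 passing singly; they passed by camera (adjusted p = 0.0128, and adjusted p = 0.382 with an estimated correlation) but not by the permutation of the mean level (-0.16; exact permutation p = 0.111, adjusted p = 0.222). Endoplasmic reticulum stress (adjusted p = 0.000348), oxidative phosphorylation (0.00277), heat shock and neuropeptide genes (each 0.00479) passed as rises by camera, with 0.370, 0.497, 0.382 and 0.370 as adjusted p with an estimated correlation, and the permutation of their mean levels did not pass (adjusted p = 0.139, 0.339, 0.174 and 0.164). Of 100 splits, the real one included, 7 gave at least 7 lists in oligodendrocytes. The other lists did not pass: other activity-induced, circadian clock, cold-inducible, adenosine and prostaglandin signalling, synaptic scaffold, sleep-regulating kinase and channel, microglial reactive, ribosomal protein and mitochondrially encoded genes.

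Oligodendrocyte precursors, measured in 18 animals, had 3 of 4488 genes risen: Erbb4, a neuregulin receptor gene (2920 ± 235 CPM, n = 8, to 3580 ± 250 CPM, n = 10; edgeR, log2 fold change 0.29, adjusted p = 0.0251, 10 of 10), Tes (0.58) and the predicted transcript Gm4876 (0.44), whose annotated span covers that of Tes and which was named after its values were seen. Microglia, in 18 animals, had 0 of 1563 genes past the edgeR threshold, 42 at an unadjusted p below 0.05, 0 by DESeq2 and 12 with no filter on low counts. All-nuclei cluster 43, in 11 animals, had 0 of 2122 past the edgeR threshold, 125 at an unadjusted p below 0.05, 0 by DESeq2 and 8 with no filter on low counts. In counts with planted changes, a log2 fold of 1 was recovered for 86% of genes in microglia and 48% in cluster 43, and a log2 fold of 0.5 for 11% and 4%. The planted genes were 200 of 1507 and 200 of 1998, a larger share than in the other classes. Recovery with fewer changed genes, where the adjustment is stricter, was not simulated.

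The labels also allowed a comparison of the sexes. In neurons 24 of 19037 genes differed between females and males, 13 higher in males and 11 higher in females. Of these 10 lay on the X chromosome, 5 on the Y and 8 on autosomes, and 1 had no position in the gene annotation. Greb1, a target gene of steroid hormone receptors (Entrez gene 268527; mm10, chromosome 12, 16670615 to 16800886), was at 4.83 ± 0.747 CPM in females (n = 9) and 16.8 ± 5.56 CPM in males (n = 10; edgeR, log2 fold change 1.79, adjusted p = 1.15e-05, higher in 10 of 10 males). Cyp19a1, which encodes aromatase, was at 4.05 ± 1.26 and 8.23 ± 2.59 CPM (1.04, adjusted p = 0.0276, 9 of 10). Whrn was higher (0.35) and Cfap299 lower (-0.74) in males. Greb1 was at 21.5 times its level in other neurons in neuronal cluster 27 and at 8.7 times in cluster 21. Cyp19a1 was at 19.6 times its level in other neurons in cluster 21. Whether the sexes differed in the shares of these clusters was not tested, so a different mix of neurons may contribute to both differences. Xist and Tsix, transcripts of the X inactivation centre, were at 1080 and 226 CPM in females and 0.179 and 1.04 CPM in males, and the Y-linked genes Uty, Kdm5d, Ddx3y and Eif2s3y were at 45.4 to 131 CPM in males and at most 0.220 CPM in females. The X-linked genes Kdm6a (-0.60), Eif2s3x (-0.59), Ddx3x (-0.55) and Kdm5c (-0.44), which escape X inactivation, were lower in males, and Sytl4 was higher (1.64). The count was 295, with all 24 shared, without normal sleep male replicate 3. It was 15 without normal sleep male replicate 4, 15 without recovery sleep male replicate 1 and 14 without recovery sleep female replicate 4.

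Whether the response to recovery sleep differed between the sexes was tested in neurons as an interaction. By edgeR 0 of 19037 genes passed, 550 had an unadjusted p below 0.05, and DESeq2 called 1. Planted interactions of log2 fold 1 were recovered for 62% of genes and those of 0.5 for 28%.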

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

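The tests of free RNA in all 3 patterns, the test of cytoplasmic RNA, the tests of the parts of cluster 9, the wider share of clusters in the astrocyte pattern, and the splits for the interaction, microglia, all-nuclei cluster 43, neuronal clusters 9 and 16 and the lists outside all neurons were chosen only after the result was seen.

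The rise of core immediate early genes in neuronal cluster 9 (0.80 on the log2 scale, 10 of 10 recovery animals above the normal sleep mean) was weighed against handling or free RNA and against a change in the make-up of the cluster. Handling or free RNA that raises these genes in every nucleus is argued against by the other 41 clusters, whose median log2 difference was -0.23 with an SD of 0.20. Normal sleep females replicates 1 and 2, with high levels outside cluster 9, enter that median. Neurons outside cluster 9 in recovery sleep (44.48 to 66.25 CPM) still lay within the range of the other normal sleep animals (42.82 to 76.52 CPM). A shift between the parts of cluster 9 is argued against by the level with parts at fixed weights, which still rose by 0.79 (standard error 0.128), against 0.02 from the mix of parts alone. The rise lay in part 11 (1.04) and was not seen in part 37 (-0.19), so more recent activity of the neurons in part 11, not of cluster 9 as a whole, may underlie it, as a hypothesis found on the same data. What stays open is whether sleep pressure, the deprivation procedure itself or warmth during sleep is the driver, since the labels give no group that separates them.

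The changes in astrocytes (245 genes, with 162 rises) were weighed against free RNA, a mix of both astrocyte clusters and a different dissection boundary. Free neuronal RNA is argued against by the risen genes themselves, whose median log2 fold change was 0.08 in all neurons and 0.52 in astrocytes, and free RNA from other classes by the change in UMIs per nucleus in oligodendrocytes, a median of 3.55% of that in astrocytes (upper quartile 20.7%), with 1 gene, Ptgds, changed by at least 75% as many UMIs per nucleus in every other class. In the larger astrocyte cluster alone, 207 of the 245 genes still passed, and 192 did with the shares of excitatory neurons and of neuronal clusters 7 and 50, the ones with striatal markers, as covariates, or 219 with clusters 4, 6 and 12, which share named genes with them, added to that share, so neither the mix of clusters nor a boundary that moves these shares accounts for the whole pattern. Chance is argued against by the 99 other splits of the animals, whose highest count was 70, though so few splits cannot exclude it. A response of astrocytes to sleep loss or to the stress of deprivation may underlie the pattern, and these remain open, untested alternatives.

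The fall of cholesterol synthesis genes in neurons and astrocytes was weighed against less cytoplasmic RNA on the nuclei, free RNA and dependence on a single library. Less cytoplasmic RNA would lower ribosomal protein genes alike: their median log2 fold change was 0.08 in astrocytes, against -0.37 for the cholesterol genes, which argues against it there, but -0.11 in neurons, against -0.27, which leaves it open there. Leaving out each of the 19 animals in turn gave an exact permutation p of at most 0.00553 for the mean list level in neurons, and of at most 0.00886 in astrocytes. Free RNA from other classes would add as many UMIs per nucleus to oligodendrocytes, whose median change was 33.6% of that in astrocytes (upper quartile 52.6%) and 42.6% of that in neurons (upper quartile 64.6%), which leaves it open in both. The set test lost its call with an estimated correlation, and time of day, feeding and the deprivation procedure cannot be separated from sleep by these labels.

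Other splits of the animals into groups of the same sizes, 100 per result with the real one included, were counted for the gene and list comparisons named here. Chance is argued against for all nuclei (1 split as large, 21 genes, highest other 1) and galanin-rich neurons (1, 37 genes, highest other 13). The same holds for astrocytes (1, 245 genes, highest other 70) and oligodendrocytes (1, 97 genes, highest other 28). It also holds for neuronal cluster 16 (1, 88 genes, highest other 51). With 100 splits the smallest possible share is 1 in 100, so chance is not excluded for these results. Few splits reached the count for inhibitory neurons (2; 2 genes, highest other 4), excitatory neurons (2; 5, highest other 5), neuronal cluster 9 (2; 29, highest other 48) and oligodendrocyte precursors (3; 3, highest other 19). Some other splits gave as many calls or more, so chance is less likely there but not excluded. The sexes (3; 24, highest other 1818) included 10 X-linked and 5 Y-linked genes, among them those that had matched the labels. A high count was thus largely set in advance, and the 8 autosomal genes were not split alone. Chance cannot be excluded for the number of lists called in neurons (67; 4 lists, highest other 12, median of the others 5), astrocytes (5; 7, highest other 9), oligodendrocytes (7; 7, highest other 8), neuronal cluster 9 (40; 3, highest other 10) and neuronal cluster 16 (70; 1, highest other 7). For the interaction (highest other 432), microglia (highest other 0) and all-nuclei cluster 43 (highest other 4) the real count was 0, so all 100 splits are as large by construction and the test says nothing. The splits with 1818, 432 and 19 genes, far above the real counts (24, 0 and 3), point to a structure of the animals whose nature was not tested.

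A single sample stood apart from its group in 11 of 128 groups checked over 32 measures, where chance gives about 1 in 20 groups. Astrocyte markers in neurons were at 548 CPM in normal sleep female replicate 3 (nearest 474) and at 466 CPM in recovery sleep male replicate 1 (nearest 486). Ribosomal protein genes in neurons were at 2770 CPM in normal sleep male replicate 5 (nearest 1730), which also had 807 CPM of Gal in cluster 16 (nearest 262) and 491 CPM in cluster 9 (nearest 147). Neurons without an inhibitory or excitatory name made up 11.2% of neurons in recovery sleep male replicate 2 (nearest 13.7%). Clusters with striatal markers made up 9.23% of neurons in normal sleep male replicate 3 (nearest 3.46%). Excitatory neurons made up 21.3% of neurons in normal sleep female replicate 3 (nearest 16.6%). Astrocytes made up 1.47% of nuclei in normal sleep male replicate 4 (nearest 7.56%), oligodendrocytes 1.87% in normal sleep female replicate 4 (nearest 10.6%), and all-nuclei cluster 43 0.553% in normal sleep female replicate 2 (nearest 0.238%). Of 48 differences between the sexes in the activity tests, 4 had an unadjusted exact permutation p below 0.05 and 0 passed adjustment.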

How the results depend on the processing

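The alternatives without the animals with few glia, with each galanin-rich cluster alone and with the share of cluster 16 as a term were chosen only after the data had been seen. Of 437 alternatives to counts of calls, 374 stayed on the same side and within 1.5 times the count, 28 gave fewer and 35 gave more. Of 20126 alternatives to single genes, clusters, shares and lists, 19436 kept their side of the threshold (350 of them, not called, with another sign), 588 lost and 100 gained the call, and 2 reversed: 1700016P03Rik, risen in the galanin-rich sum, was at -0.27 in cluster 16 alone, and Pappa, fallen in the sum, was at 0.09 in cluster 9 alone. DESeq2 called 76 genes in all nuclei, 25 in inhibitory neurons, 19 in excitatory neurons, 5 in oligodendrocyte precursors, 48 between the sexes and 1 interaction. Nuclei with at least 2000 UMIs gave 10 genes in all nuclei and 36 in oligodendrocytes. With no filter on low counts the calls were 417 in astrocytes, 185 in oligodendrocytes, 114 in galanin-rich neurons, 12 in microglia and 8 in all-nuclei cluster 43. Galanin-rich neurons gave 19 genes with no term for sex and 88 (20 shared) in cluster 16 alone. Oligodendrocyte precursors gave 5 genes with doublets kept and 11 with the replicate block. The sexes differed in 13 genes without the animals with few glia. With an estimated correlation 0 lists were called in neurons. For the activity measure, Fos alone gave 0 clusters in all neurons and 0 of the galanin-rich clusters, resolution 0.8 gave 2 clusters and resolution 3 gave 3, and relative to other neurons resolution 0.8 gave 2. The replicate block, signs flipped within pairs of equal number, gave 0 of 42 clusters, and such pairs cannot give a p below 0.00391. Of 9 recovery animals, 2 correlated best with the normal sleep animal of their own number. Correlations within the 9 pairs ran from -0.16 to 0.324. So few pairs do not settle whether more than the number is shared. Except for the clusters in that block, whose fewer assignments limit p, the cause was not tested.

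Leaving out each animal in turn gave these lowest and highest counts: all nuclei 12 to 27, inhibitory neurons 1 to 5, excitatory neurons 5 to 8, galanin-rich neurons 11 to 38, astrocytes 184 to 259, oligodendrocytes 63 to 112, oligodendrocyte precursors 1 to 6, microglia 0 to 0, all-nuclei cluster 43 0 to 0, the sexes 14 to 295, the interaction 0 to 0, lists in neurons 4 to 7, clusters with a changed activity level 1 to 3, galanin-rich clusters with a changed activity level 2 to 2, the same relative to other neurons 1 to 2, Gal level 0 to 0 and class shares 0 to 0. Single animals whose absence moved a count by over 1.5 times were recovery sleep male replicate 5 in all nuclei (12), normal sleep male replicate 4 in excitatory neurons (8), recovery sleep female replicate 4 (11), recovery sleep male replicate 3 (15) and normal sleep female replicate 1 (20) in galanin-rich neurons, and recovery sleep female replicate 4 (63) and recovery sleep male replicate 3 (64) in oligodendrocytes. Between the sexes they were normal sleep male replicate 3 (295), normal sleep male replicate 4 (15), recovery sleep male replicate 1 (15) and recovery sleep female replicate 4 (14), and for lists normal sleep male replicates 1 and 2 (7 each). For clusters with a changed activity level they were normal sleep male replicate 2 (3), normal sleep female replicate 3 (3), recovery sleep male replicate 3 (2) and recovery sleep female replicate 2 (2). Relative to other neurons, 2 galanin-rich clusters were called without normal sleep male replicate 5 or normal sleep female replicate 4. The small counts in inhibitory neurons and oligodendrocyte precursors moved by over 1.5 times without 8 and 11 of the animals. The setting with at least 2000 UMIs could not be fitted in microglia and cluster 43, nor could some fits of cluster 43 with an animal left out, where too few animals remained. At the depth and number of animals of microglia and cluster 43, 200 changed genes were planted in each. Log2 folds of 0.5 were recovered for 11% and 4% of genes and those of 1 for 86% and 48%. Recovery with fewer changed genes and the share owed to depth alone were not tested.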

Other observations

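The split of cluster 9 into parts, the tests of its parts, the description of further genes and the tests of free RNA were chosen only after the result was seen.

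Clustering at resolution 3 divided most of cluster 9 into part 11 (2493 nuclei) and part 37 (1424 nuclei). Core immediate early genes rose in part 11, from 90.5 ± 23.3 CPM (n = 9) to 187 ± 36.3 CPM (n = 10; log2 difference 1.04, exact permutation p = 0.000126, 10 of 10 above the normal sleep mean). In part 37 they were at 45.3 ± 10.8 and 40 ± 11 CPM (log2 difference -0.19, exact permutation p = 0.249), and the difference between the parts passed its own test (1.23, exact permutation p = 0.000567). Part 11 had more Gal (191.0 against 73.9 CPM), Calcr (103.1 against 50.5), Th, the tyrosine hydroxylase gene (13.2 against 1.7), and Sntb1 (122.9 against 4.2), together with Col8a1 and the serotonin receptor gene Htr7. Part 37 had more Esr1 (35.8 against 17.7 CPM), and Gli3, Cdh8 and the muscarinic receptor gene Chrm3. In cluster 16 the parts had log2 differences of -0.24 (exact permutation p = 0.206) and -0.77 (exact permutation p = 0.0417). The first was at 44.3 ± 16.5 CPM (n = 8) and 35.2 ± 6.58 CPM (n = 10), with -0.59 in females and 0.10 in males. The second was at 103 ± 84.5 CPM (n = 8) and 48.4 ± 12.4 CPM (n = 10), with -1.46 in females and -0.09 in males.

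Further genes of glia passed adjusted over their lists alone and not over all genes. In astrocytes these were Gfap, an intermediate filament gene (log2 fold change -0.54), and the clock gene Rora (0.31). In oligodendrocytes the clock genes Ciart (-0.67), Per3 (-0.46) and Dbp (-0.52) passed adjusted over the list alone, with the clock time of collection not given, as did Ptgds (0.63), the adenosine receptor gene Adora1 (0.40) and Adk (-0.27), whose sign was opposite to that in astrocytes. In cluster 9 the activity-induced genes Pcsk1, Sorcs3 and Homer1 passed adjusted over the list alone, and that list rose by camera (adjusted p = 0.0209, and adjusted p = 0.0530 with an estimated correlation).

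Free RNA from other classes, which would give each class the same UMIs per nucleus, was tested for Opalin, the myelin genes and Mbp alone in neurons and for Ptgds in astrocytes. Opalin in astrocytes was at 97.5% of its level in neurons in normal sleep and 122% in recovery sleep, but in oligodendrocyte precursors at 97.5% and 181%, from 37 and 33 UMIs, too few to decide. The myelin genes were at a median of 106% and 107% in astrocytes and 97.4% and 103% in precursors, but Mbp at 63.9% and 62.6% in astrocytes, which leaves its excess in neurons open, and at 97.3% and 80.8% in precursors. Ptgds in neurons was at 96.6% and 97.7% of its level in astrocytes, and in precursors at 96.2% and 99.6%. Free RNA may therefore account for the changes in Ptgds and in the myelin list apart from Mbp, and for Opalin as far as astrocytes show; which class released it was not tested.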
